A study of Arabidopsis thaliana with 6 samples.

How the data were processed

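RNA was measured by sequencing in 6 libraries of Arabidopsis thaliana root-tip protoplasts from seedlings 7 days old, 2 each from sorted gates for G1 (2n), S (between 2n and 4n) and G2M (4n). Per the labels, the plants were Col-0 with reporters for H2B and CDT1A, total RNA was amplified with a SMART-Seq v4 kit, and libraries were made with an Ovation Ultralow V2 kit. A gate on DNA content does not separate dividing cells from cells that have stopped dividing at the same DNA content. Trimmomatic 0.39, HISAT2 2.2.1 and featureCounts on the TAIR10 genome are credited to the submitters' processing notes, while the version of featureCounts, its options, the strandedness and the handling of reads that map to several places are not given in the sources used here. Values of genes that overlap others on the opposite strand, and of near-identical copies such as histones, ribosomal proteins and the pair GSTU24 and GSTU25, are therefore uncertain.

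The first deposited table holds, per the labels and its whole numbers, the raw read count of each of 32833 genes in each library, made by the authors without normalization. Of these genes 32548 are in the TAIR10.1 annotation and 285 belong to the plastid and mitochondrial genomes. The other deposited table, named TPM by the authors, holds values in another unit. Its columns sum to between 0.000498 and 0.0075, its largest value is 0.000484, and no gene has a mean of at least 1. Its zeros are those of the count table in 100% of cases. Its ratio to the counts repeats every 17 lines, with an SD of the log2 ratio of 0.00274, against 2.13 or more at the other periods from 2 to 40 (28894 genes, 2 libraries). Such values cannot be compared between libraries or genes, so TPM was recomputed from the counts and the exon lengths of the annotation.

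Total counts per library ran from 13114711 to 208406910. A floor of 3 counts was worth from 0.0144 CPM in S replicate 1 to 0.229 CPM in S replicate 2. Reads without molecular identifiers are not independent molecules, so such floors cover counting error only. The pair of libraries of each gate differed by more than sampling noise, with a chi-square per degree of freedom of 28.6 in G1, 15.0 in S and 6.86 in G2M, so no pair agreed within that noise, as copies of 1 library would. Separate libraries of this depth are expected to exceed counting noise, so the check serves only to find duplicates. The SD of the log2 difference within a pair was 0.668 in G1, 1.25 in S and 0.917 in G2M.

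Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the default filterByExpr filter, which left 25364 genes, and quasi-likelihood F tests in 1 fit of the 3 gates to the 6 libraries. The common dispersion was 0.0555 and the prior degrees of freedom were 9.45. P-values were adjusted by the Benjamini-Hochberg method per comparison, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. With 2 libraries per gate an exact permutation test of 1 gene cannot give a p below 0.333, so calls rest on the spread shared across genes. On simulated data with 100 genes changed by each fold, edgeR recovered 55%, 48% and 69% (2-fold) and 85%, 85% and 91% (4-fold) for S versus G1, G2M versus S and G2M versus G1. Median log2 sizes at 2-fold were 0.95, 1.00 and 1.03. False calls were 10 of 24902, 9 of 24872 and 8 of 24912 genes tested. The data had more called genes, so rates there may differ.

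The comparisons, their tests, the rule for named genes and most alternatives were set before the data were examined, as were the 26 gene lists named in the text and the figure. All but the kinesins and cytosolic ribosomal proteins were matched to the annotation by identifier and symbol, which kept 402 members. Kinesins and ribosomal proteins were instead found by searching gene descriptions, with symbols or synonyms also used for the latter. Ribosomal genes were left out if organelle genomes encode them or if the description or synonyms name plastid, chloroplast or mitochondrion. Nuclear genes of organelle ribosomal proteins without such words may remain in the list called cytosolic. A check of names dropped 5 members, and 5 members that the matching moved to unrelated genes with the same symbol (EOL1, SCL28, ENDO4, BOP1 and PEP) were left out, a deviation from the written rule. Lists were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation between genes of 0.01, adjusted over the 78 tests of 26 lists in 3 comparisons. Camera compares the genes of a list with all other genes. Results for 3 list members are not reported here, while the tests and counts of the lists include them.

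Genes were named by a rule. In each comparison it takes the 6 largest log2 fold changes in each direction among genes that passed, whose libraries did not overlap between gates, with a mean of at least 10 CPM in the higher gate and a symbol in the annotation, leaving out plastid and mitochondrial genes. It adds the 2 members of each list with the smallest p among those that passed, and from both glutathione lists the member with the highest CPM. It always includes CDT1A, PCNA1, CYCB1;1, CDKB2;1, KNOLLE, GSH1, GSH2, GR1 and CYCD3;1. For genes highest in a gate it takes the 5 with the largest smaller fold change. Genes whose call rested on 1 library or on zero counts were passed over as examples where others served. A gene counts as highest in a gate when it passed above each of the other gates, and the count for independent comparisons is the product of both shares.

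Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in all libraries, a replicate block, limma-voom with quality weights, removal of plastid and mitochondrial genes, glmTreat against a 1.5-fold change, fits of only the compared gates, and leaving out each library in turn. For the lists, camera with an estimated correlation and fry, directional and mixed, were run. Added after the data were seen were thinning all libraries to the smallest total of 13114711 counts, limma on log2 of recomputed TPM with pseudocounts of 1 and 0.1, offsets for GC content and exon length, and the list members as first matched. An exploratory test of gene families, set after the values were seen, was also run and is not reported. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9.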

Results

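RNA was sequenced from protoplasts, which are cells freed from their walls, of Arabidopsis thaliana root tips from seedlings 7 days old. The plants carried fluorescent reporters of histone H2B and of CDT1A, a protein that licenses replication origins. Protoplasts were sorted by DNA content as a stand-in for cell cycle phase, with a 2n gate for G1, a gate between 2n and 4n for S and a 4n gate for G2M. Each gate has 2 libraries, 6 in all. Counts summed over genes came to 128604597 and 61572560 in the G1 libraries (replicates 1 and 2), 208406910 and 13114711 in the S libraries and 15947211 and 31629519 in the G2M libraries. Between 25696 and 30029 genes per library had at least 1 count. Across genes, which are not independent replicates, Pearson's r of log2 CPM within a pair was 0.973 in G1, 0.932 in S and 0.966 in G2M. S replicate 2 had r = 0.940 and 0.946 with the G2M libraries and 0.935 with each G1 library, all above its r with the other S library. With log2 TPM its r was 0.973 with the other S library, against 0.975 and 0.976 with G2M and 0.965 and 0.963 with G1, so the order against G1 turned. Mitochondrial genes took 8.23% and 6.53% of the counts in G1, 3.67% and 3.10% in S and 2.94% and 3.13% in G2M, mostly from 1 gene, ATMG00020. All levels below are CPM after TMM scaling, given as mean ± SD over n = 2 libraries per gate. Positions are on the build TAIR10.1.

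The comparison of S with G1 asks which transcripts differ between cells that are copying their DNA and cells with unreplicated DNA. Mitotic cyclins, kinases and activators rose in the S gate in 28 of 29 cases. CYCB1;1 (AT4G37490, chromosome 4, 17621886 to 17624308), a B-type cyclin of mitotic entry, rose by 3.82 ± 0.15 (log2 fold change ± SE) from 4.55 ± 0.454 to 64.7 ± 3.20 CPM (edgeR adjusted p = 1.88e-08). CDKB2;1 (AT1G76540, chromosome 1, 28720328 to 28722550), a mitotic cyclin-dependent kinase, rose by 4.09 ± 0.19 from 4.96 ± 1.37 to 85.7 ± 8.21 CPM. KNOLLE (AT1G08560, chromosome 1, 2709525 to 2711000), the syntaxin of cytokinesis, rose by 3.64 ± 0.25 from 4.93 ± 2.2 to 62.5 ± 7.25 CPM. The largest rises by the naming rule included DRP5A (AT1G53140, chromosome 1, 19799188 to 19802675), a dynamin-related protein, which rose by 5.09 ± 0.17 from 5.03 ± 0.0587 to 171 ± 16.9 CPM, and ROPGEF6 (5.16 ± 0.41), an activator of ROP GTPases. Of 30 replication genes 19 fell, while CDT1B, POLD1, LIG1 and FEN1 rose and 7 did not pass. CDT1A (AT2G31270, chromosome 2, 13328862 to 13331831) fell by 1.18 ± 0.17 from 153 ± 7.25 to 68.6 ± 20.5 CPM (edgeR adjusted p = 4.52e-04), with counts that hold reads of the CDT1A reporter if those were assigned to the gene. In every named gene called changed in any comparison, both libraries of the higher gate lay above both libraries of the lower gate.

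Of 29 tested mitotic cyclins, kinases and activators of the anaphase-promoting complex, 28 rose from G1 to S and none fell (median log2 change 3.03, camera adjusted p = 4.66e-26, or 0.510 with an estimated correlation). All 29 rose when adjusted over the list alone, while over all genes CYCA2;3 did not pass. The largest changes in the list included CYCB1;2 (4.87 ± 0.20) and CYCA1;1 (4.88 ± 0.17). Genes named here only because 5 or fewer members of a list rose, fell or did not pass were chosen after their values were seen. Among genes of the spindle, the phragmoplast and mitotic chromosomes, 17 of 18 rose, all but HTR12, and none fell (median log2 change 3.14, camera adjusted p = 2.40e-15, or 0.510 with an estimated correlation). All 18 rose adjusted over the list alone. MAP65-3, a microtubule bundler of the phragmoplast, rose by 4.16 ± 0.17 (log2 fold change ± SE) from 3.97 ± 0.0407 to 71.3 ± 11 CPM. Of 28 kinesins 20 rose (21 adjusted over the list alone) and none fell, among them ATK5 (4.37 ± 0.18) and AT1G72250 (3.78 ± 0.18) (median log2 change 1.34, camera adjusted p = 7.65e-11, or 0.510 with an estimated correlation). Cohesin and condensin genes rose in 8 of 13 cases (9 adjusted over the list alone), while SYN3 and CTF7 fell (median log2 change 0.68, camera adjusted p = 0.0185, or 0.520 with an estimated correlation). AT3G57060, listed as a condensin subunit, rose by 3.56 ± 0.21 from 4.52 ± 0.279 to 52.8 ± 13.5 CPM. The cohesin and condensin list no longer passed without S replicate 2 (camera adjusted p = 0.164), and 5 members rose without G1 replicate 2, where 0 fell, as without G1 replicate 1. With offsets for GC content and exon length 4 of its members rose.

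Ribosome biogenesis rose with the mitotic genes. In that list 16 of 17 genes rose, all but GAR1, and all 17 did adjusted over the list alone (median log2 change 0.81, camera adjusted p = 8.35e-09, or 0.510 with an estimated correlation). NUC1 (AT1G48920, chromosome 1, 18098081 to 18101732), a nucleolin of the nucleolus, rose by 1.02 ± 0.11 (log2 fold change ± SE) from 722 ± 25.2 to 1467 ± 107 CPM (edgeR adjusted p = 6.87e-05). Cytosolic ribosomal proteins did not pass as a list (median 0.08, camera adjusted p = 0.462), with 8 of 46 rising and RPS15A, AT1G57540 and RPS28 falling, and their median was −0.12 with upper-quartile factors and −0.07 without S replicate 2. Those counts moved with single libraries, with 1 rising and 1 falling without G1 replicate 1, 2 rising and 0 falling without G1 replicate 2, and 1 falling without G2M replicate 1 or without G2M replicate 2. They moved with the scaling too, with 7 falling under upper-quartile factors and 15 rising with GC and length offsets. Of 30 DNA replication genes 19 fell (21 adjusted over the list alone), while CDT1B, POLD1, LIG1 and FEN1 rose (median log2 change −0.66, camera adjusted p = 1.07e-04, or 0.520 with an estimated correlation). SLD5, a subunit of the GINS helicase complex, fell by 1.41 ± 0.18 from 23.9 ± 0.989 to 8.92 ± 0.532 CPM. PCNA1, the sliding clamp, fell by 0.60 ± 0.14 from 113 ± 2.01 to 75.4 ± 14.7 CPM (edgeR adjusted p = 0.00933), a call lost without G1 replicate 1 (adjusted p = 0.0522) and without G1 replicate 2 (adjusted p = 0.0673). In the list, 10 genes fell and 2 rose without G1 replicate 1, and 12 fell and 2 rose without G1 replicate 2.

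Replication-dependent histones fell in 7 of 28 cases (9 adjusted over the list alone) and none rose (median log2 change −0.28, camera adjusted p = 0.00201, or 0.648 with an estimated correlation), with AT5G10390, a histone H3 gene, falling by 1.08 ± 0.19 and AT3G46320, a histone H4 gene, falling by 0.76 ± 0.14. Histone genes have near-identical copies, so a read may fit several of them, and the reporter may add reads to H2B genes. That list no longer passed without S replicate 1 (camera adjusted p = 0.0776). Its falling members numbered 3 without G1 replicate 1, 3 without G1 replicate 2, 4 without S replicate 1, where 2 rose, and 14 with upper-quartile factors. With GC and length offsets 3 rose and 2 fell. Among inhibitors of cyclin-dependent kinases and endocycle regulators 4 of 15 fell, KRP3, KRP5, CCS52A1 and CCS52A2, and none rose (median log2 change −0.38, camera adjusted p = 0.00347, or 0.510 with an estimated correlation); 2 fell without G1 replicate 2. CCS52A2 fell by 1.58 ± 0.23 (log2 fold change ± SE) from 23.7 ± 2.08 to 8.28 ± 2.93 CPM. G1 cyclins and the RBR and E2F genes went both ways (median −0.23, camera adjusted p = 0.164), with CYCD1;1, CYCD2;1 and CYCD3;2 rising and CYCD3;1, CYCD4;1, CYCD4;2 and RBR1 falling. CYCD3;1 fell by 0.67 ± 0.17, a call lost without G1 replicate 1 (edgeR adjusted p = 0.192). Of these 17 genes 1 fell without G1 replicate 1, 2 without G1 replicate 2, 2 without G2M replicate 2 and 7 with upper-quartile factors.

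Glutathione S-transferases, which attach glutathione to other molecules, fell from G1 to S in 11 of 17 cases, over all genes and adjusted over the list alone, and none rose (median log2 change −0.54, camera adjusted p = 2.65e-05, or 0.510 with an estimated correlation). Without G1 replicate 1 the falling members numbered 7. GSTU25 (AT1G17180, chromosome 1, 5872024 to 5873124), the most abundant of them in G1, fell by 0.76 ± 0.12 (log2 fold change ± SE) from 2219 ± 123 to 1306 ± 101 CPM (edgeR adjusted p = 5.82e-04). GSTF8 fell by 1.46 ± 0.13 from 986 ± 73.0 to 358 ± 4.68 CPM. Genes for glutathione synthesis, recycling and breakdown did not pass as a list (median −0.14, camera adjusted p = 0.127). In that list 6 of 22 genes fell and GSH2, AT3G54660 and GRXS17 rose, with 4 rising adjusted over the list alone, 1 rising without G1 replicate 1 and 0 without G1 replicate 2. GPX2, a glutathione peroxidase-like enzyme, fell by 0.93 ± 0.13 from 108 ± 3.61 to 56.9 ± 1.63 CPM. GSH1 (AT4G23100, chromosome 4, 12102135 to 12107695), the enzyme of the first step of glutathione synthesis, did not pass at −0.17 ± 0.13 (adjusted p = 0.413), but it passed at −0.35 with upper-quartile factors and at −0.38 with GC and length offsets. GSH2, the enzyme of the second step, rose by 0.55 ± 0.13 from 40.6 ± 2.66 to 59.6 ± 4.26 CPM (adjusted p = 0.00960), a call lost without G1 replicate 2 (adjusted p = 0.117). The glutathione reductase GR1 did not pass at 0.42 ± 0.14 (adjusted p = 0.0514), but passed without S replicate 1 (adjusted p = 0.0103), with DESeq2 (0.0379), without a filter on low counts (0.0416), without plastid and mitochondrial genes (0.0488), with thinned libraries (0.0319) and with recomputed TPM (0.0146 to 0.0363).

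Markers of cell types moved between the G1 and S gates too, beside the mitochondrial share, which was lower in both S libraries than in both G1 libraries. Of 4 root cap regulators SMB, BRN1 and FEZ fell and BRN2 did not pass, with the same count adjusted over the list alone (median log2 change −0.69, camera adjusted p = 0.0207, or 0.520 with an estimated correlation). SMB fell by 1.04 ± 0.18 (log2 fold change ± SE) from 94.8 ± 23.0 to 46.1 ± 2.16 CPM. The root cap list no longer passed without G1 replicate 1 (camera adjusted p = 0.0558) and without S replicate 1 (camera adjusted p = 0.125). Phloem and pericycle markers did not pass as a list (median −0.37, camera adjusted p = 0.0847), but passed without S replicate 1 (camera adjusted p = 0.0164), where 5 fell. CALS7, NAC045 and NAC086 fell, NAC045 by 3.96 ± 0.38 and NAC086 by 4.58 ± 0.60, the latter at 0.425 ± 0.601 CPM in S. Xylem markers did not pass (median 0.28, camera adjusted p = 0.576), their median being −0.49 without S replicate 1 and −0.03 with GC and length offsets. ACL5, TMO5, LHW and PHB rose among them, and 2 rose without G1 replicate 1 or with upper-quartile factors. Root hair and epidermis markers (median 0.87, camera adjusted p = 0.697), with GL2 and EGL3 rising and WER falling, and endodermis and cortex markers (median 0.70, camera adjusted p = 0.564) did not pass. In the endodermis and cortex list 0 of 7 genes were called by edgeR, 0 at an unadjusted p below 0.05, 0 by DESeq2 and 1 by limma-voom. Regulators of the stem cell niche and of regeneration did not pass as a list (median 0.43, camera adjusted p = 0.258), while BBM, PLT2, PLT3 and SHR rose and RGF2 fell. SHR rose by 0.92 ± 0.17 from 26.6 ± 5.85 to 50.6 ± 7.32 CPM.

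Of 25 wounding and protoplasting genes WRKY40, ERF1A and LOX3 fell and none rose, and the list did not pass (median −0.19, camera adjusted p = 0.0907). It passed without S replicate 2 (camera adjusted p = 0.0227), where 6 fell, while 1 fell without G1 replicate 1, 1 without G1 replicate 2 and 9 with upper-quartile factors. Heat shock proteins passed, with HSP17.6A, HSP17.6II and HSP17.4 falling among 7 (median log2 change −0.87, camera adjusted p = 0.0225, or 0.522 with an estimated correlation). That call was lost without any of G1 replicate 1 (camera adjusted p = 0.0938), G1 replicate 2 (0.0716), S replicate 2 (0.357), G2M replicate 1 (0.0543) and G2M replicate 2 (0.0538). Falling heat shock genes numbered 0 without either G1 library, 1 without S replicate 2 and 1 with GC and length offsets. Chromatin assembly and DNA methylation genes did not pass (median 0.33, camera adjusted p = 0.248), with 6 of 20 rising, among them DDM1 (1.18 ± 0.13) and CMT3 (1.08 ± 0.12), and FAS1, FAS2 and ATXR6 falling. Falling members were 5 with upper-quartile factors. DNA repair and checkpoint genes did not pass either (median 0.25, camera adjusted p = 0.462), and their median was −0.11 with GC and length offsets. Of 22 repair genes 8 rose, among them PARP1 (1.30 ± 0.17), and BARD1 and MSH7 fell. Rising repair genes numbered 5 without G1 replicate 1 and 4 without G1 replicate 2, and falling ones 4 without S replicate 2, 5 with upper-quartile factors and 6 with GC and length offsets.

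Nucleotide supply genes did not pass (median −0.15, camera adjusted p = 0.858), with RNR1, TSO2 and DUT1 falling among 8. DUT1, which removes dUTP, fell by 1.38 ± 0.19 (log2 fold change ± SE) from 121 ± 11.8 to 47.2 ± 15.2 CPM. Only 1 of these genes fell without G1 replicate 1, without G1 replicate 2, without S replicate 1 or without G2M replicate 1. Replacement histones (median −0.02, camera adjusted p = 0.848) did not pass, with AT4G40040 rising and HTA9 falling among 6, and their median was 0.13 with GC and length offsets. Expansins and xyloglucan enzymes (median −0.29, camera adjusted p = 0.179) did not pass, with EXPA15, XTH9 and XTH16 rising and 6 of 25 falling, or 2 falling without G1 replicate 1. XTH9 rose by 1.53 ± 0.15 and EXPA17 fell by 1.28 ± 0.17. Aquaporins (median 0.29, camera adjusted p = 0.735) did not pass, with PIP1;1 and PIP2;7 rising and PIP2;4 falling among 14. Their median was −0.33 without S replicate 1, 4 rose without S replicate 2, and 0 rose or fell without G1 replicate 1.

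Of the genes named for small counts between S and G1, 37 lost the call in at least 1 of the fits without 1 library. Of these 14 lost it without a G2M library, which does not enter the comparison, at 0.97 to 1.03 times the log2 fold change of all libraries, so there the spread or the threshold moved and not the fold. Over all losses the median was 0.97 times. Below, a pair of ranges of adjusted p gives the fit without replicate 1 first. The fold shrank by over 1.5 times for CCS52A1, AT1G57540, XTH16, AT3G54660 and TSO2 without S replicate 1 (0.40 to 0.63 times), PIP2;7, HSP17.6A and TMO5 without S replicate 2 (0.55 to 0.62) and TMO5 and PHB without G1 replicate 1 (0.59 and 0.58). Without either G1 library PIP1;1, PIP2;7, CCS52A1, SYN3, CTF7, RPS15A, AT1G57540, MSH7, CDT1B, POLD1, XTH16, CYCD2;1, CYCD4;1, CYCD4;2, AT3G54660, GRXS17, HSP17.6A, HSP17.6II, HSP17.4, RNR1, TSO2, BRN1, PLT3, RGF2 and ERF1A lost their calls, and so did PIP2;4, CYCD3;1, WRKY40, TMO5 and PHB without G1 replicate 1, and KRP5, RPS28, BARD1, GSH2, PLT2, LOX3 and LHW without G1 replicate 2 (edgeR adjusted p from 0.0501 to 0.317 and 0.0510 to 0.483). Without S replicate 1 PIP1;1, CCS52A1, CTF7, RPS15A, AT1G57540, MSH7, POLD1, XTH16, CYCD4;2, AT3G54660, RNR1, TSO2, RGF2 and ERF1A lost their calls (0.0510 to 0.234). Without S replicate 2 PIP2;7, CDT1B, HSP17.6A, HSP17.6II, PLT3 and TMO5 lost their calls (0.0559 to 0.182). Without either G2M library PIP1;1, CCS52A1, CTF7, RPS15A, AT1G57540, XTH16, CYCD4;1, RNR1, BRN1, PLT3 and ERF1A lost their calls, and so did CDT1B and TSO2 without G2M replicate 1, and CYCD4;2 without G2M replicate 2 (0.0517 to 0.140 and 0.0538 to 0.111). With GC and length offsets HSP17.6A and RPS28 lost their calls (0.0861 and 0.0522), HSP17.6A also with unfiltered recomputed TPM (0.117). Fitted with only the gates compared, PIP2;7 and GSH2 lost theirs (0.0877 and 0.0688).

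Between S and G1, 5373 of 25364 genes passed edgeR at an adjusted p below 0.05, 3526 rising and 1847 falling, so that 65.6% of the changed genes rose. With upper-quartile factors 2399 rose and 3026 fell, a share of 44.2%, and with a filter of at least 1 CPM in all libraries the share was 53.8%. The median change over all genes was 0.08, and −0.10 with upper-quartile factors, so small list medians are relative to that shift. The count was 2862 without G1 replicate 1 and 2753 without G1 replicate 2. Of 26 lists 11 passed camera, and 0 passed with an estimated correlation. The directional test of fry, which does not set a list against other genes, ended the calls of replication-dependent histones (adjusted p = 0.157) and heat shock proteins (0.150) and passed glutathione synthesis, recycling and breakdown (0.00792, down) and chromatin assembly and DNA methylation (0.0279, up). The p-values measure only the spread between libraries, which may be technical, since the labels do not say that the libraries came from separate plant cultures.

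The comparison of G2M with S asks what differs once replication is complete. Genes listed as cytosolic ribosomal proteins rose in 38 of 46 cases and replication genes in 18 of 30. Histones fell in 22 of 28 cases, glutathione S-transferases in 8 of 17, with GSTU4 rising, and root cap genes in 4 of 4. RPS28, a protein of the small ribosomal subunit, rose by 0.81 ± 0.13 (log2 fold change ± SE) from 117 ± 8.97 to 205 ± 7.49 CPM (edgeR adjusted p = 0.00131). MCM6 (AT5G44635, chromosome 5, 18006212 to 18010667), a subunit of the replicative helicase, rose by 1.01 ± 0.13 from 39.4 ± 2.53 to 79.1 ± 5.33 CPM (adjusted p = 2.93e-04). CDT1A rose by 1.13 ± 0.17 from 68.6 ± 20.5 to 148 ± 8.16 CPM, reporter reads included if they were assigned to the gene. GSTU25 fell by 1.77 ± 0.12 from 1306 ± 101 to 384 ± 14.7 CPM (adjusted p = 3.65e-06). BRN1 (AT1G33280, chromosome 1, 12072611 to 12073965), a transcription factor of root cap maturation, fell by 1.83 ± 0.12 from 188 ± 1.15 to 53.0 ± 0.756 CPM (adjusted p = 3.61e-06). Mitotic genes did not pass as a list, and CDKB2;1 did not pass at 0.08 ± 0.17 (adjusted p = 0.754).

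Of 46 genes listed as cytosolic ribosomal proteins 38 rose (41 adjusted over the list alone) and none fell (1 adjusted over the list alone). Their median log2 change was 0.56 (camera adjusted p = 2.22e-11, or 0.510 with an estimated correlation). Without G2M replicate 1 the rising members numbered 9, and without G2M replicate 2 they numbered 4. Ribosome biogenesis genes rose in 13 of 17 cases (15 adjusted over the list alone), all but NUC2, NOF1, SWA1 and BRX1-1 (median log2 change 0.56, camera adjusted p = 1.09e-06, or 0.510 with an estimated correlation), against 3 without G2M replicate 1 and 7 without G2M replicate 2. NUC1 rose by 0.70 ± 0.11 (log2 fold change ± SE) from 1467 ± 107 to 2386 ± 50.5 CPM. CBF5, the pseudouridine synthase of the nucleolus, rose by 0.77 ± 0.12. Of 30 replication genes 18 rose (20 adjusted over the list alone) and none fell (median log2 change 0.66, camera adjusted p = 9.49e-09, or 0.510 with an estimated correlation), against 11 rising without G2M replicate 1 and 9 without G2M replicate 2. CDT1B, the second CDT1 gene, rose by 1.10 ± 0.16 from 25.4 ± 3.90 to 54.0 ± 2.81 CPM. PCNA1 rose by 0.56 ± 0.14 from 75.4 ± 14.7 to 110.0 ± 3.75 CPM (edgeR adjusted p = 0.0180). That call was lost without S replicate 1 (adjusted p = 0.0766), without G2M replicate 1 (0.0969) and without G2M replicate 2 (0.131). Nucleotide supply passed, and the genes that rose among 8 included RNR1 and DUT1 (median log2 change 0.39, camera adjusted p = 0.0207, or 0.510 with an estimated correlation), a call lost without S replicate 1 (camera adjusted p = 0.0918). Of these genes 1 rose without S replicate 1 and 1 without G2M replicate 2. RNR1, the large subunit of ribonucleotide reductase, rose by 0.93 ± 0.13.

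Replication-dependent histones fell from S to G2M in 22 of 28 cases, over all genes and adjusted over the list alone, and none rose (median log2 change −0.66, camera adjusted p = 6.54e-07, or 0.521 with an estimated correlation), against 3 falling without G2M replicate 1. AT3G53730, a histone H4 gene, fell by 0.98 ± 0.14 (log2 fold change ± SE) from 66.2 ± 2.39 to 33.5 ± 4.69 CPM. HTA7, a histone H2A gene, fell by 0.83 ± 0.12. Reads may be shared between histone copies. Replacement histones did not pass (median −0.17, camera adjusted p = 0.735), with AT4G40040, AT5G10980 and HTA11 falling and HTA9 rising among 6, while 0 fell without G2M replicate 1 and 1 without G2M replicate 2. Chromatin assembly and DNA methylation passed with FAS1, FAS2, ASF1B, SUVH5 and ATXR6 rising among 20 (median log2 change 0.27, camera adjusted p = 0.00201, or 0.510 with an estimated correlation). FAS1, a subunit of chromatin assembly factor 1, rose by 1.10 ± 0.20 from 8.83 ± 1.70 to 18.5 ± 0.847 CPM. Rising chromatin genes numbered 3 without S replicate 1, 2 without G2M replicate 1 and 1 without G2M replicate 2. DNA repair and checkpoint genes did not pass (median 0.09, camera adjusted p = 0.182), but passed without S replicate 2 (camera adjusted p = 0.0472), and their median was −0.15 with GC and length offsets. Genes that rose included BARD1, KU70, MSH6 and MSH7, and GMI1 fell, while 3 rose without G2M replicate 1 or with GC and length offsets, and 2 without G2M replicate 2. BARD1 rose by 1.56 ± 0.30 from 23.4 ± 12.7 to 65.8 ± 15.3 CPM.

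Mitotic cyclins, kinases and activators did not pass as a list between S and G2M (median 0.13, camera adjusted p = 0.182), with CYCB1;4, CYCB2;3, CYCB2;4, UBC19 and UBC20 rising and CYCA2;3 and CYCA2;4 falling among 29. The list passed without G2M replicate 2 (camera adjusted p = 0.0294), 9 rose without S replicate 2, 1 rose without G2M replicate 1, and its median was −0.01 with recomputed TPM and −0.00 without S replicate 1. CYCB1;1 did not pass at 0.34 ± 0.14 (edgeR adjusted p = 0.0991), but passed with DESeq2 (0.0346), limma-voom (0.0347) and without S replicate 2 (0.0371). KNOLLE did not pass at 0.51 ± 0.22 (edgeR adjusted p = 0.119), but passed with DESeq2 (0.0393), limma-voom (0.00675), only the gates compared (0.0309), and without G1 replicate 1 (0.0376) or G1 replicate 2 (0.0378). Spindle, phragmoplast and mitotic chromosome genes did not pass (median 0.27, camera adjusted p = 0.115), with AT4G14330, 3xHMG-box1 and TAN rising among 18. That list passed without G1 replicate 1 (camera adjusted p = 0.0378), without G1 replicate 2 (0.0378) and without G2M replicate 2 (0.0130), while 1 member rose without S replicate 1 and 0 without either G2M library or with GC and length offsets. Kinesins did not pass (median 0.15, camera adjusted p = 0.182), but passed without G2M replicate 2 (camera adjusted p = 0.0312), and their median was −0.09 with GC and length offsets. ZWI, AT4G24175 and AT4G26660 rose and AT4G39050 fell among 28 kinesins, against 1 rising without S replicate 1, 6 rising and 3 falling without S replicate 2, 0 rising without G2M replicate 1, 1 rising without G2M replicate 2, and 0 rising and 3 falling with GC and length offsets. Cohesin and condensin genes did not pass (median 0.12, camera adjusted p = 0.190), and their median was −0.08 with GC and length offsets. Of 13 such genes edgeR called 0, against 6 at an unadjusted p below 0.05, 2 by DESeq2, 6 by limma-voom and 6 without S replicate 2.

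G1 cyclins and the RBR and E2F genes did not pass from S to G2M (median 0.41, camera adjusted p = 0.115), with CYCD2;1, CYCD3;2, RBR1 and CDKA;1 rising and CYCD3;1 and E2FB falling among 17. Of them 7 rose without S replicate 2, and 1 rose without any other single library. RBR1, the retinoblastoma-related repressor, rose by 1.02 ± 0.15 (log2 fold change ± SE) from 46.5 ± 8.43 to 93.3 ± 1.37 CPM. CYCD3;1 fell by 0.60 ± 0.18 (edgeR adjusted p = 0.0327), a call lost without S replicate 1 (adjusted p = 0.125), without G2M replicate 1 (0.269) and without G2M replicate 2 (0.120). Inhibitors of cyclin-dependent kinases and endocycle regulators did not pass (median 0.05, camera adjusted p = 0.784), with a mean of −0.05 on the other side of 0 and medians of −0.01 and −0.05 with recomputed TPM. CCS52A2 rose and KRP7 and SMR4 fell among 15, while 5 rose without S replicate 2 and 0 without S replicate 1 or either G2M library.

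Glutathione S-transferases fell from S to G2M in 8 of 17 cases, over all genes and adjusted over the list alone, while GSTU4 rose, as 2 did adjusted over the list alone (median log2 change −0.82, camera adjusted p = 0.0144, or 0.522 with an estimated correlation). The list no longer passed without S replicate 2 (camera adjusted p = 0.0539) and without G2M replicate 1 (0.148). GSTU24, which shares much of its sequence with GSTU25, fell by 1.22 ± 0.13 (log2 fold change ± SE) from 71.1 ± 0.519 to 30.4 ± 1.02 CPM. Genes for glutathione synthesis, recycling and breakdown did not pass as a list (median 0.15, camera adjusted p = 0.956), and their mean of −0.17 and the camera direction, down, were opposite to the median, which was −0.01 with recomputed TPM. GR1, OXP1 and GRXS17 rose and GPX2, GPX6, GGT1, GGCT2;1 and GRX480 fell, as 6 did adjusted over the list alone. Rising members numbered 5 without S replicate 2, 0 without G2M replicate 1 and 1 without G2M replicate 2. GPX2 fell by 1.23 ± 0.13 from 56.9 ± 1.63 to 24.3 ± 2.11 CPM. GR1, a glutathione reductase, rose by 0.69 ± 0.14 from 80.0 ± 12 to 129 ± 0.830 CPM (edgeR adjusted p = 0.00536), a call lost without G2M replicate 1 (adjusted p = 0.0577). GSH1 did not pass at −0.02 ± 0.13 (adjusted p = 0.913), and GSH2 did not pass at 0.20 ± 0.13 (adjusted p = 0.292).

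Cell-type markers moved between S and G2M and the mitochondrial share was 3.67% and 3.10% in the S libraries and 2.94% and 3.13% in the G2M libraries. All 4 root cap regulators, SMB, BRN1, BRN2 and FEZ, fell, also adjusted over the list alone (median log2 change −1.61, camera adjusted p = 0.00142, or 0.510 with an estimated correlation). BRN2 fell by 2.13 ± 0.13 (log2 fold change ± SE) from 116 ± 4.96 to 26.5 ± 0.768 CPM. Xylem markers did not pass (median 0.25, camera adjusted p = 0.0633), but passed without S replicate 1 (camera adjusted p = 0.0159) and without G2M replicate 1 (0.0119), and XCP1, XCP2 and LHW rose. XCP2, a cysteine protease of xylem cells, rose by 3.13 ± 0.54 from 1.07 ± 0.846 to 10.9 ± 3.49 CPM. Phloem and pericycle markers did not pass (median −0.15, camera adjusted p = 0.688), with only APL falling among 11 and the camera direction, up, opposite to the median. Their median was 0.33 without S replicate 1 and 0.08 without G2M replicate 1, and 0.16 with DESeq2. Root hair and epidermis markers did not pass (median 0.22, camera adjusted p = 0.526), with GL2 rising and EXPA18, which had 0 counts in G2M, falling among 7, a mean of −1.31 opposite to the median, and medians of −0.02 without S replicate 2 and −0.04 without G2M replicate 1. Endodermis and cortex markers did not pass (median −0.07, camera adjusted p = 0.858), with a mean of 0.43 and a camera direction, up, opposite to the median. In that list edgeR called 0 of 7, against 3 at an unadjusted p below 0.05, 2 by DESeq2 and 3 by limma-voom. Regulators of the stem cell niche and of regeneration did not pass (median −0.25, camera adjusted p = 0.848), their median being 0.03 without S replicate 2 and 0.03 without G2M replicate 2. SCR rose and WOX11 and RGF3 fell, while 3 rose and 4 fell without S replicate 2. With GC and length offsets the fall of RGF3 shrank from −0.94 to −0.33 and its call was lost (edgeR adjusted p = 0.273). SCR, a regulator of the niche and the endodermis, rose by 1.49 ± 0.24 from 6.84 ± 1.14 to 19.5 ± 3.79 CPM.

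Wounding and protoplasting genes fell in 9 of 25 cases and none rose, with the same counts adjusted over the list alone (median log2 change −0.38, camera adjusted p = 0.0207, or 0.520 with an estimated correlation). ZAT12, a stress-induced zinc finger gene, fell by 1.62 ± 0.17 (log2 fold change ± SE) from 317 ± 27.2 to 103 ± 28.1 CPM. The list no longer passed without S replicate 2 (camera adjusted p = 0.319), where 3 rose, and without G2M replicate 1 (0.134), where 5 fell. Heat shock proteins did not pass (median −0.78, camera adjusted p = 0.0847), but passed without S replicate 2 (camera adjusted p = 0.0467), with HSP101, HSP17.6A and HSP17.4 falling among 7. Aquaporins passed with PIP1;4, PIP2;1 and PIP2;7 rising among 14, or 5 adjusted over the list alone (median log2 change 0.76, camera adjusted p = 0.0152, or 0.510 with an estimated correlation), a call lost without S replicate 2 (camera adjusted p = 0.132). Rising aquaporins numbered 5 without S replicate 1 and 1 without G2M replicate 2. PIP2;7 rose by 0.93 ± 0.14 from 181 ± 30.6 to 345 ± 14.4 CPM. Expansins and xyloglucan enzymes did not pass (median −0.36, camera adjusted p = 0.849), with EXPA6, XTH9, XTH15 and XTH16 rising and 6 of 25 falling. Without G2M replicate 1, 2 rose and 1 fell, and without G2M replicate 2, 1 rose and 3 fell. The largest rise by the naming rule was that of PAL1, a gene of phenylpropanoid synthesis, which rose by 3.27 ± 0.43 from 2.22 ± 1.41 to 18.4 ± 5.48 CPM.

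Between G2M and S, 53 such genes lost the call in at least 1 of these fits, 12 of them without a G1 library, at 0.98 to 1.01 times the fold, and the median over all losses was 0.97 times. The fold shrank by over 1.5 times for CCS52A2, GRXS17, HSP17.6A, DUT1, APL and LHW without S replicate 1 (0.44 to 0.66 times), CYCA2;4 and HTA11 without S replicate 2 (0.65 and 0.49), GPX6 and HTA11 without G2M replicate 1 (0.59 and 0.66) and GSTU4 without G2M replicate 2 (0.43). Without either G1 library GMI1, CYCD2;1, CYCD3;2, CDKA;1, E2FB, GRXS17, AT4G24175, UBC19, CYCA2;3, HTA11, EXPA18 and LHW lost their calls (edgeR adjusted p from 0.0534 to 0.0761 and 0.0527 to 0.0804). Without either S library GMI1 lost its call, and so did CCS52A2, ASF1B, SUVH5, KU70, EXPA6, CYCD2;1, CYCD3;2, CDKA;1, CYCD3;1, GSTU4, OXP1, GRXS17, GPX6, HSP17.6A, AT4G24175, AT4G26660, UBC19, CYCA2;3, DUT1, APL, HTA9, FEZ, AT4G14330, TAN, WOX11 and LHW without S replicate 1, and CYCA2;4 and HTA11 without S replicate 2 (0.0526 to 0.231 and 0.0620 to 0.210), and EXPA18 was not tested without S replicate 1. Without either G2M library CCS52A2, SMR4, FAS2, ASF1B, SUVH5, KU70, GMI1, EXPA6, XTH16, CYCD2;1, CYCD3;2, CDKA;1, CYCD3;1, E2FB, OXP1, GRXS17, ZWI, AT4G24175, AT4G39050, UBC19, CYCA2;3, CYCA2;4, APL, HTA9, AT4G40040, HTA11, EXPA18, AT4G14330, 3xHMG-box1, TAN and LHW lost their calls, and so did GR1, GPX6, HSP17.6A, AT4G26660, CYCB1;4, CYCB2;3, CYCB2;4, AT5G10980, GL2 and WOX11 without G2M replicate 1, and PIP1;4, PIP2;1, KRP7, ATXR6, MSH7, XTH9, GSTU4, GGCT2;1, DUT1 and FEZ without G2M replicate 2 (0.0565 to 0.414 and 0.05005 to 0.455). With GC and length offsets ZWI, 3xHMG-box1, AT4G14330 and EXPA18 lost their calls (0.0602 to 0.131), as the first 3 did with recomputed TPM (0.0630 to 0.154). EXPA18 lost its call with upper-quartile factors (0.0571), and EXPA18, APL and DUT1 did with unfiltered recomputed TPM (0.0703 to 0.334).

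Between G2M and S, 4960 of 25364 genes passed edgeR, 2399 rising and 2561 falling, so that 48.4% of the changed genes rose. With RLE factors 3026 rose and 2422 fell, a share of 55.5%, and with DESeq2 the share was 55.4%, so the majority turns with the scaling. With recomputed TPM the share was 35.1%, and against a 1.5-fold change (glmTreat) 89 rose and 783 fell, a share of 10.2%. The median change over all genes was −0.10, and −0.14 with upper-quartile factors. The count was 9378 without S replicate 2, 1472 without G2M replicate 1 and 1797 without G2M replicate 2. Of 26 lists 10 passed camera, and 0 passed with an estimated correlation. The directional test of fry ended the call of aquaporins (adjusted p = 0.0903) and passed G1 cyclins and RBR-E2F (0.0410, up) and glutathione synthesis, recycling and breakdown (0.0279, down).

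The comparison of G2M with G1 spans the largest difference in DNA content. Mitotic cyclins, kinases and activators rose in 28 of 29 cases, cytosolic ribosomal proteins in 37 of 46 and ribosome biogenesis genes in 17 of 17. Histones fell in 25 of 28 cases, glutathione S-transferases in 12 of 17, root cap genes in 4 of 4 and wounding genes in 13 of 25. CYCB1;1 rose by 4.16 ± 0.16 (log2 fold change ± SE) from 4.55 ± 0.454 to 81.7 ± 5.77 CPM (edgeR adjusted p = 8.07e-09). NUC1 rose by 1.72 ± 0.12 from 722 ± 25.2 to 2386 ± 50.5 CPM (adjusted p = 2.77e-07). GSTU25 fell by 2.53 ± 0.12 from 2219 ± 123 to 384 ± 14.7 CPM (adjusted p = 3.37e-08). HTA6 (AT5G59870, chromosome 5, 24115354 to 24116220), a histone H2A gene, fell by 1.19 ± 0.14 from 138 ± 1.47 to 60.5 ± 10.7 CPM (adjusted p = 2.21e-05). BRN1 fell by 2.17 ± 0.12 from 239 ± 12 to 53.0 ± 0.756 CPM (adjusted p = 7.57e-08). Replication genes did not pass as a list, and CDT1A did not pass at −0.05 ± 0.17 (adjusted p = 0.842), although it passed at −0.44 with GC and length offsets. PCNA1 did not pass at −0.04 ± 0.14 (adjusted p = 0.821).

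**Figure D1:**
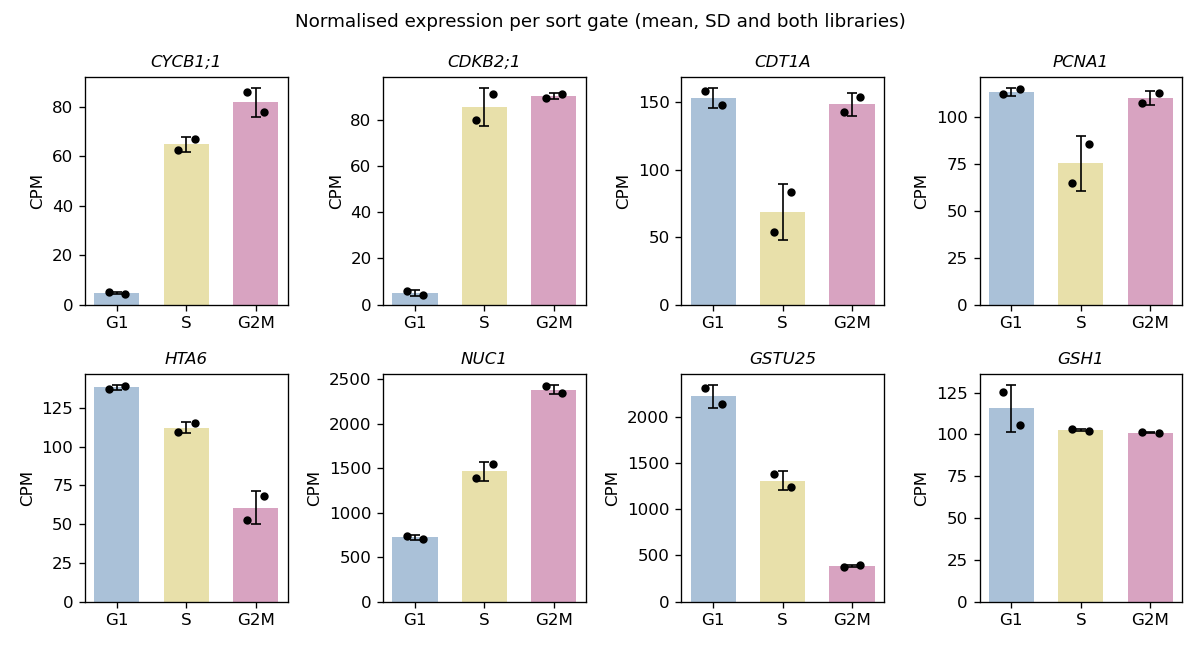
Expression of 8 genes in the G1, S and G2M gates, in CPM after TMM scaling, with bars for the mean, error bars for the SD and points for the 2 libraries of each gate. CYCB1;1 was at 4.55 CPM in G1 and 81.7 CPM in G2M, while CDT1A was at 153 CPM in G1, 68.6 CPM in S and 148 CPM in G2M.

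From G1 to G2M, 28 of 29 mitotic cyclins, kinases and activators rose, all but CYCA2;3, with the same count adjusted over the list alone (median log2 change 2.99, camera adjusted p = 1.52e-17, or 0.510 with an estimated correlation). CDKB2;1 rose by 4.17 ± 0.19, KNOLLE by 4.15 ± 0.25 and CYCB2;4 by 4.82 ± 0.18. Of 18 spindle, phragmoplast and mitotic chromosome genes 17 rose, all but HTR12, also adjusted over the list alone (median log2 change 3.40, camera adjusted p = 7.65e-11, or 0.510 with an estimated correlation). MAP65-3 rose by 4.56 ± 0.17 and 3xHMG-box2 by 3.44 ± 0.15. Of 28 kinesins 22 rose (23 adjusted over the list alone), among them ATK5 (4.78 ± 0.19), and AT4G39050 fell (median log2 change 0.92, camera adjusted p = 1.44e-08, or 0.510 with an estimated correlation). Cohesin and condensin genes rose in 9 of 13 cases (10 adjusted over the list alone) and none fell (median log2 change 0.80, camera adjusted p = 0.00452, or 0.520 with an estimated correlation), against 4 rising with GC and length offsets. SCC3, a cohesin subunit, rose by 1.21 ± 0.13 (log2 fold change ± SE) from 51.6 ± 1.02 to 119 ± 4.53 CPM. The largest rises by the naming rule were those of CYCB1;2 (5.38 ± 0.21), DRP5A (5.16 ± 0.17) and ROPGEF6 (5.09 ± 0.41).

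All 17 ribosome biogenesis genes rose from G1 to G2M, also adjusted over the list alone (median log2 change 1.39, camera adjusted p = 2.85e-09, or 0.510 with an estimated correlation). AT5G27120, annotated as a NOP56-like protein, rose by 1.85 ± 0.13 (log2 fold change ± SE) from 326 ± 28.7 to 1179.8 ± 22.7 CPM. Cytosolic ribosomal proteins rose in 37 of 46 cases and only RPL18AA fell, with the same counts adjusted over the list alone (median log2 change 0.58, camera adjusted p = 1.94e-08, or 0.520 with an estimated correlation). RPL5B rose by 1.11 ± 0.12 from 1061 ± 16.3 to 2289.8 ± 19.0 CPM. Replication genes did not pass as a list (median 0.09, camera adjusted p = 0.275), and their median was −0.13 with upper-quartile factors, −0.39 with GC and length offsets and −0.03 with recomputed TPM. In that list 8 of 30 rose and CDC6A, PCNA2 and SLD5 fell. Without 1 library the counts were 4 rising and 1 falling (G1 replicate 1), 5 and 1 (G1 replicate 2), 4 and 0 (G2M replicate 1), and 5 rising without G2M replicate 2. With upper-quartile factors 5 rose and 5 fell, and with GC and length offsets 3 rose and 10 fell. CDT1B rose by 1.67 ± 0.15 from 17 ± 0.136 to 54.0 ± 2.81 CPM. Nucleotide supply did not pass (median 0.57, camera adjusted p = 0.187), with TK1A and DUT1 falling among 8. Genes that rose included RNR1 and TK1B, and 2 rose without G1 replicate 2 or without G2M replicate 1.

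Replication-dependent histones fell from G1 to G2M in 25 of 28 cases, all but HTA3, HTA12 and HTB1, also adjusted over the list alone (median log2 change −0.93, camera adjusted p = 4.90e-08, or 0.520 with an estimated correlation). AT5G59690, a histone H4 gene, fell by 1.19 ± 0.15 (log2 fold change ± SE) from 192 ± 2.52 to 83.8 ± 19.9 CPM. Replacement histones did not pass (median −0.25, camera adjusted p = 0.588), with HTR4 rising and AT5G10980 and HTA11 falling among 6, a median of 0.07 with GC and length offsets and 4 falling with upper-quartile factors. AT5G10980 no longer passed without G2M replicate 1 (edgeR adjusted p = 0.0607), nor did HTA11 without G1 replicate 2 (adjusted p = 0.0551) or without G2M replicate 1 (0.169). Chromatin assembly and DNA methylation genes rose in 10 of 20 cases and none fell, also adjusted over the list alone, with 4 falling under GC and length offsets (median log2 change 0.49, camera adjusted p = 0.00551, or 0.510 with an estimated correlation). VIM3, a protein of DNA methylation, rose by 1.45 ± 0.13 from 25.3 ± 0.505 to 68.9 ± 0.621 CPM. DNA repair and checkpoint genes rose in 10 of 22 cases and GMI1 fell (median log2 change 0.38, camera adjusted p = 0.0306, or 0.510 with an estimated correlation), but their median was −0.21 with GC and length offsets. That list no longer passed without G1 replicate 2 (camera adjusted p = 0.0528) and with libraries thinned to 1 depth (0.0501). Its rising members numbered 6 without G1 replicate 1 or with upper-quartile factors, 5 without G2M replicate 1 and 4 with GC and length offsets. PARP1 rose by 1.47 ± 0.17 and KU70 by 1.12 ± 0.13.

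Inhibitors of cyclin-dependent kinases and endocycle regulators passed with KRP3, KRP6, KRP7, SMR4 and CCS52A2 falling among 15 (median log2 change −0.65, camera adjusted p = 0.0313, or 0.510 with an estimated correlation). SMR4 lost its call at −0.73 with GC and length offsets (edgeR adjusted p = 0.0697). The list no longer passed with libraries thinned to 1 depth (camera adjusted p = 0.0617), without S replicate 2 (0.0551), without G2M replicate 1 (0.102) and without G2M replicate 2 (0.0633). Falling members numbered 3 without G1 replicate 2 or G2M replicate 1 and 2 without G2M replicate 2. G1 cyclins and the RBR and E2F genes did not pass (median 0.06, camera adjusted p = 0.760), with a mean of −0.08 and medians of −0.16 with upper-quartile factors, −0.01 with GC and length offsets and −0.05 without G2M replicate 2. CYCD1;1, CYCD2;1, CYCD3;2 and DPA rose, and CYCD3;1, CYCD5;1, CYCD6;1, CYCD7;1 and E2FB fell. Falling members were 2 without G1 replicate 1, 3 without G1 replicate 2, 2 without G2M replicate 1 and 1 without G2M replicate 2, and rising ones were 2 without G1 replicate 2 or G2M replicate 1. CYCD3;1, a D-type cyclin, fell by 1.27 ± 0.18 (log2 fold change ± SE) from 31.4 ± 5.18 to 12.9 ± 1.07 CPM (edgeR adjusted p = 8.97e-05), and CYCD3;2 rose by 1.13 ± 0.13.

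Glutathione S-transferases fell from G1 to G2M in 12 of 17 cases, all but GSTF2, GSTF9, GSTU4, GSTU13 and GSTU20, and none rose, also adjusted over the list alone (median log2 change −1.44, camera adjusted p = 1.19e-04, or 0.510 with an estimated correlation). GSTU24 fell by 2.05 ± 0.13 (log2 fold change ± SE) from 126 ± 7.76 to 30.4 ± 1.02 CPM. Genes for glutathione synthesis, recycling and breakdown did not pass as a list (median −0.11, camera adjusted p = 0.462), and their median was 0.02 with GC and length offsets. In that list 8 of 22 fell and GSH2, GR1, AT3G54660, OXP1 and GRXS17 rose, or 6 adjusted over the list alone and 8 with GC and length offsets. GSH2 rose by 0.75 ± 0.13 from 40.6 ± 2.66 to 68.5 ± 3.10 CPM (edgeR adjusted p = 5.45e-04), and GR1 rose by 1.11 ± 0.14 from 59.5 ± 6.84 to 129 ± 0.830 CPM (adjusted p = 4.49e-05). GSH1 did not pass at −0.19 ± 0.13 (adjusted p = 0.236), but it passed at −0.41 with upper-quartile factors, −0.42 with the 1 CPM filter, −0.31 with recomputed TPM and −0.51 with GC and length offsets.

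Root cap regulators fell with these genes, and the mitochondrial share was lower in both G2M libraries than in both G1 libraries. All 4 root cap genes fell, also adjusted over the list alone (median log2 change −2.27, camera adjusted p = 0.00225, or 0.510 with an estimated correlation). BRN2 fell by 2.37 ± 0.13 (log2 fold change ± SE) from 137 ± 13.2 to 26.5 ± 0.768 CPM. Wounding and protoplasting genes fell in 13 of 25 cases (14 adjusted over the list alone) and none rose (median log2 change −0.58, camera adjusted p = 0.00451, or 0.520 with an estimated correlation), against 7 falling without G2M replicate 1. ZAT12 fell by 2.10 ± 0.17 from 442 ± 32.4 to 103 ± 28.1 CPM. Heat shock proteins passed with HSP101, HSP17.6A, HSP18.2, HSP17.4 and HSFA2 falling among 7 (median log2 change −1.29, camera adjusted p = 0.0189, or 0.520 with an estimated correlation). HSP17.4 fell by 3.69 ± 0.42 from 6.58 ± 0.792 to 0.501 ± 0.0493 CPM. Xylem markers rose in 6 of 11 cases (7 adjusted over the list alone) and none fell (median log2 change 0.73, camera adjusted p = 0.0306, or 0.520 with an estimated correlation), a call lost without G2M replicate 2 (camera adjusted p = 0.0892). ACL5 rose by 1.61 ± 0.21 from 42.6 ± 14.4 to 129 ± 10.5 CPM. Phloem and pericycle markers did not pass (median −0.69, camera adjusted p = 0.462), with CVP2 rising and APL, BRX, CALS7, NAC045 and NAC086 falling among 11, while 4 rose without S replicate 2. With a filter of at least 1 CPM in all libraries their median was 0.11. NAC045 fell by 4.81 ± 0.43 from 15.7 ± 3.71 to 0.601 ± 0.281 CPM.

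Root hair and epidermis markers did not pass from G1 to G2M (median 0.41, camera adjusted p = 0.529), with a mean of −0.76 opposite to the median, which was −0.25 without G2M replicate 2 and −0.02 with unfiltered recomputed TPM. RHD6, GL2 and EGL3 rose and COBL9 and WER fell among 7, WER with its call lost at −0.18 with GC and length offsets (edgeR adjusted p = 0.332). GL2, a regulator of cells without root hairs, rose by 2.08 ± 0.19 (log2 fold change ± SE) from 12.8 ± 3.38 to 54.4 ± 4.67 CPM. Endodermis and cortex markers did not pass (median 1.23, camera adjusted p = 0.564), with MYB36 and AT1G62500 rising among 7, or 0 adjusted over the list alone, and a median of −0.21 without G2M replicate 2. The call of MYB36 was lost without either G1 library (adjusted p = 0.140 and 0.244) and without either G2M library (0.160 and 0.145). The call of AT1G62500 was lost without G1 replicate 2 (adjusted p = 0.0947) and without either G2M library (0.0539 and 0.105), and both calls with upper-quartile factors (0.0608 and 0.0510). Regulators of the stem cell niche and of regeneration did not pass (median 0.18, camera adjusted p = 0.559), with a mean of −0.11 and a median of −0.04 with upper-quartile factors. In that list 7 of 17 rose and WOX11, RGF2 and RGF3 fell, against 5 falling without either S library and 4 rising with GC and length offsets. SCR rose by 2.01 ± 0.24 and SHR by 1.40 ± 0.17. Expansins and xyloglucan enzymes did not pass (median −0.52, camera adjusted p = 0.542), with EXPA15, XTH9, XTH15 and XTH16 rising and 8 of 25 falling. EXPA17 fell by 2.98 ± 0.18 and XTH9 rose by 2.31 ± 0.16. Aquaporins rose in 6 of 14 cases (9 adjusted over the list alone) and PIP2;4 fell (median log2 change 1.38, camera adjusted p = 0.0460, or 0.520 with an estimated correlation). Their call was lost with libraries thinned to 1 depth (camera adjusted p = 0.0750), without G1 replicate 1 (0.0858) and without G2M replicate 2 (0.0614), and 10 rose without either S library. PIP2;7 rose by 1.47 ± 0.14 from 124 ± 8.27 to 345 ± 14.4 CPM.

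**Figure D2:**
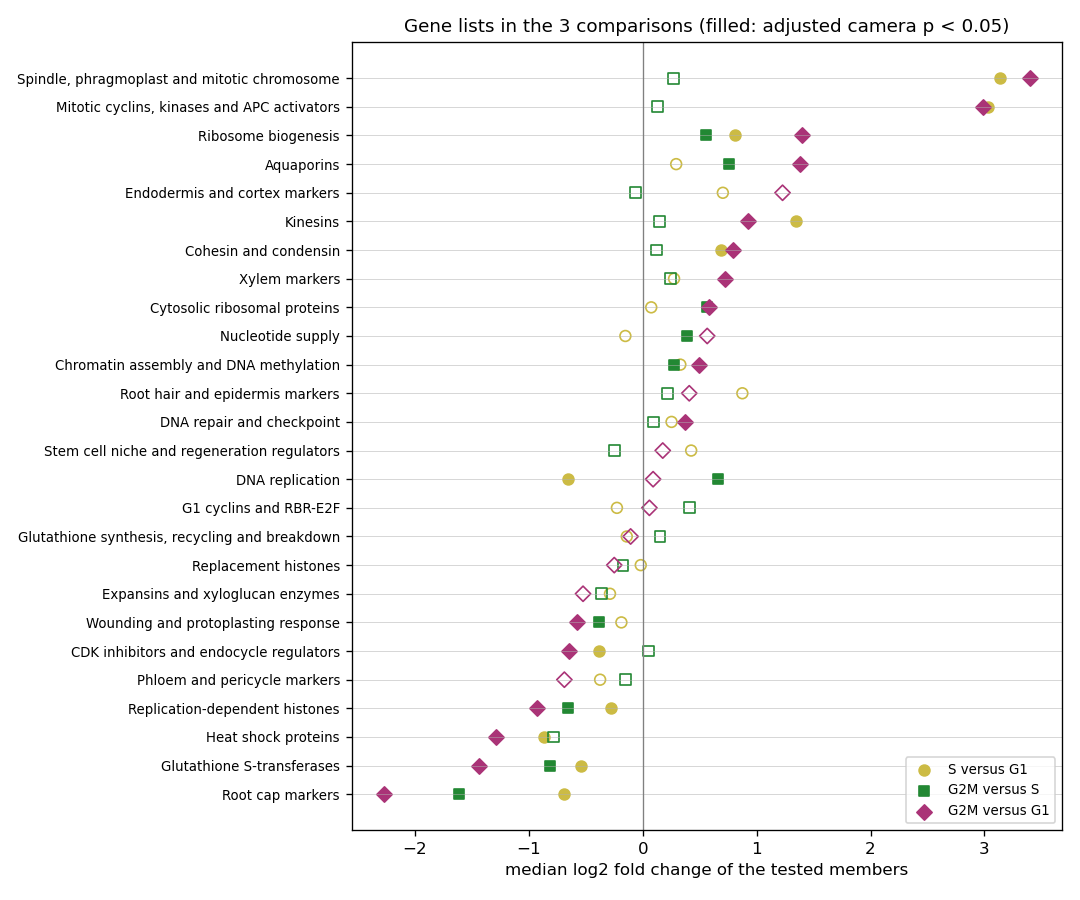
Median log2 fold change of 26 gene lists in the comparisons S versus G1, G2M versus S and G2M versus G1, with points filled where the camera adjusted p was below 0.05. The mitotic list had medians of 3.03, 0.13 and 2.99 in the 3 comparisons, the middle one being −0.01 with recomputed TPM, and the glutathione S-transferase list had medians of −0.54, −0.82 and −1.44.

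Between G2M and G1, 30 such genes lost the call in at least 1 of these fits, at a median of 0.89 times the fold. The fold shrank by over 1.5 times for CYCD7;1 without G1 replicate 1 or G2M replicate 2 (0.61 and 0.64 times), AT1G62500 and OXP1 without G1 replicate 2 (0.61 and 0.66) and CDC6A and PCNA2 without G2M replicate 1 (0.47 and 0.61). Without either G1 library CDC6A, PCNA2, MYB36, DPA, CYCD6;1, E2FB, TK1B, HTR4 and COBL9 lost their calls, and so did KRP7, CYCD7;1, AT4G39050, TK1A, CVP2 and RHD6 without G1 replicate 1, and KRP3, CCS52A2, AT1G62500, CYCD1;1, OXP1, RNR1, DUT1 and HTA11 without G1 replicate 2 (edgeR adjusted p from 0.0507 to 0.350 and 0.0510 to 0.244). Without either G2M library KRP3, CCS52A2, MYB36, AT1G62500, DPA, CYCD5;1, CYCD6;1, E2FB and TK1B lost their calls, and so did RPL18AA, CDC6A, PCNA2, SLD5, CYCD1;1, OXP1, HSP18.2, RNR1, TK1A, DUT1, CVP2, AT5G10980, HTA11, RHD6 and COBL9 without G2M replicate 1, and KRP7, CYCD7;1, HSFA2, AT4G39050, BRX and HTR4 without G2M replicate 2 (0.0539 to 0.457 and 0.0501 to 0.276).

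Between G2M and G1, 10226 of 25364 genes passed edgeR, 5882 rising and 4344 falling, so that 57.5% of the changed genes rose. With upper-quartile factors 4443 rose and 5650 fell, a share of 44.0%. The median change over all genes was −0.14, and −0.36 with upper-quartile factors. The count was 6679 without G2M replicate 1. Of 26 lists 16 passed camera, and 0 passed with an estimated correlation. The directional test of fry ended the call of aquaporins (adjusted p = 0.0659) and passed glutathione synthesis, recycling and breakdown (0.00363, down) and nucleotide supply (0.0279, up).

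The study sorts cells by DNA content to find transcripts of each phase, so genes higher in 1 gate than in each of the other gates were counted. In G1, 1366 genes were highest, against 316 for independent comparisons. They include NAC045, NAC086, HVA22F, SUS5 and APX5. NAC045 was at 15.7 ± 3.71 CPM in G1, 0.901 ± 0.387 in S and 0.601 ± 0.281 in G2M. APX5 lost its calls against both gates with DESeq2. In S, 130 genes were highest, against 356 for independent comparisons. YUC9 was at 115 ± 6.01 CPM in G1, 220.2 ± 19.5 in S and 50.2 ± 0.129 in G2M. YUC9 makes auxin and WAG2 is a kinase of auxin transport. WAG2, PUB18, BRU6 and CLV1 completed the set of 5 named for S, but CLV1 no longer passed against G1 without G1 replicate 2 (edgeR adjusted p = 0.0910), or with GC and length offsets (0.0627), or against G2M without G2M replicate 1 (0.118) or G2M replicate 2 (0.135), and passed against neither gate with unfiltered recomputed TPM (0.0857 and 0.0879). In G2M, 1966 genes were highest, against 556 for independent comparisons. PAL1 was at 1.25 ± 0.262 CPM in G1, 2.22 ± 1.41 in S and 18.4 ± 5.48 in G2M. EXT3, XCP2, GASA1 and PIP2;1 were also among the 5 named for G2M, and GASA1 and PIP2;1 lost the call against S without G2M replicate 2 (adjusted p = 0.249 and 0.0900), PIP2;1 also with DESeq2 (0.0957) and with GC and length offsets (0.0508). Both lost it with unfiltered recomputed TPM (0.0959 and 0.0726).

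By list, 34 of 46 cytosolic ribosomal proteins and 13 of 17 ribosome biogenesis genes were highest in G2M. Of 17 glutathione S-transferases 10 were highest in G1, and of 30 replication genes 14 were lowest in S. The 2 comparisons behind each count share the libraries of that gate, so part of the excess over independent comparisons in G1 and G2M may come from those libraries. Simulated unchanged groups gave 0 such genes in each of 10 draws, but they also gave 0 calls in each single comparison, so they do not show how much the shared libraries add. The count for G1 was 615 without G1 replicate 1 and 782 without G1 replicate 2. The count for S was 67 without G1 replicate 1, 43 without G1 replicate 2, 389 without S replicate 2, 29 without G2M replicate 1 and 28 without G2M replicate 2. The count for G2M was 1233 without S replicate 1, 3698 without S replicate 2, 332 without G2M replicate 1 and 476 without G2M replicate 2.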

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

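Thinning, recomputed TPM, GC and length offsets and the list members as first matched were chosen only after the data were seen, and the other alternatives were planned. The 3 alternatives set in advance that use the deposited TPM table were not run, because its values are not comparable between libraries, and recomputed TPM took their place.

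Over all alternatives, list tests kept their side of the threshold in 895 of 1014 cases, gained 53 calls, lost 66 and reversed in 0. Named genes kept theirs in 4604 of 4828, gained 44 calls, lost 179 and reversed in 1. Direction was not compared where neither fit passed, nor in fry's mixed test. The reversal was NAC086 between G2M and S, which rose by 7.90 without S replicate 1 (edgeR adjusted p = 0.0427), against a range from −1.23 to that value without single libraries. The S library left there held 0 CPM of NAC086, so the size depends on the prior count.

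Testing against a 1.5-fold change with glmTreat, which asks for more than a difference from 0, left 1210 genes for S versus G1, 872 for G2M versus S and 5016 for G2M versus G1. It left 343 genes highest in G1, 58 in G2M and 4 in S, the last being YUC9, BRU6, AT4G01910 and AT5G02430, the latter pair chosen after their values were seen. With limma-voom 9893 genes passed for G2M versus S, and 2197, 741 and 3728 genes were highest in G1, S and G2M. Upper-quartile factors gave 2249 genes highest in G1. A filter of at least 1 CPM in all libraries gave 2104 highest in G1 and 230 in S. Recomputed TPM gave 301 genes highest in S, or 284 with the smaller pseudocount, and without a filter 204 in S and 871 in G2M. The cause of these shifts was not tested. With an estimated correlation camera passed 0, 0 and 0 lists in S versus G1, G2M versus S and G2M versus G1, where the smallest adjusted p was 0.510, while fry's mixed test, which asks only whether genes of a list change, passed 25, 22 and 25, and its directional test 11, 11 and 17. With 2 libraries per gate the correlation within a list is poorly known, and camera that estimates it had little power. By that test even the spindle list for S versus G1 had an unadjusted p of 0.0216. With log2 TPM Pearson's r across genes was 0.973 within S and 0.990 within G2M.

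Leaving out 1 library gave 2753 to 6276 genes for S versus G1, 1472 to 9378 for G2M versus S and 6679 to 12720 for G2M versus G1. Genes highest in G1 ranged from 615 to 1699, in S from 28 to 389 and in G2M from 332 to 3698, and lists passing from 9 to 10, 9 to 13 and 13 to 16. The lone library left in a gate is assumed to vary like the other gates. A block for the replicate number gave 5016, 4248 and 9660 genes, 12, 10 and 16 lists, and 1275, 112 and 1764 genes highest in G1, S and G2M. Deviations of libraries with the same number correlated at −0.046 (G1 and S), 0.031 (G1 and G2M) and −0.065 (S and G2M) across genes, so they gave no sign of a shared day. The lists with their 5 moved members kept in gave the same calls in 78 of 78 tests. Depth limits the lowest genes most in S replicate 2, where 3 counts are 0.229 CPM.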

Other observations

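All tests in this part except that of depth for the spread between the S libraries were chosen only after the result was seen.

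Of 30 replication genes 19 were lower in the S gate than in G1 and 4 were higher. Depth does not account for all of it, since the median of the list was −0.68 with all libraries thinned to 1 total. GC content and exon length do not either, since the median was −0.86 with offsets for both. An exchange of the G1 and S labels would put mitotic genes higher in G1, and the mitotic list instead had a median of 3.03 for S minus G1. An exchange of the S and G2M labels cannot be told apart from the labels as given. It would put histones as high or higher in the libraries labelled G2M, and the histone median was −0.66 for G2M minus S, with 22 of 28 falling but 3 without G2M replicate 1. Yet 18 of 30 replication genes rose from S to G2M (median 0.66), as an exchange would have it, the mitotic list moved little (median 0.13), and 7 histones were highest in G1 and 0 in S. What stays open is what the S gate holds besides replicating cells, such as cells that are past the start of S, and the gate itself as a biological difference, both untested.

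Root cap genes were lower in G2M than in G1 in 4 of 4 cases, glutathione S-transferases in 12 of 17 and wounding genes in 13 of 25. Depth does not account for the fall of the glutathione S-transferases, since their median was −1.46 with all libraries thinned to 1 total. The medians of root cap and wounding genes were then −2.34 and −0.59. A loss of root cap cells with no other change of cell types would move xylem and phloem markers alike, but 6 xylem markers rose and 0 fell, while 1 phloem marker rose and 5 fell (Fisher's exact test, two-sided p = 0.0152). Without single libraries this p ran from 0.0079 to 0.0476, with 4 phloem markers rising and 5 falling without S replicate 2, and it was 0.143 with a filter of at least 1 CPM in all libraries, which left fewer markers. The test treats genes as independent, and the phloem list did not pass camera (adjusted p = 0.462). Another mix of cell types in each gate may be behind the change. The root cap median of −2.27 is part of the pattern itself, so it does not test this. Such a mix cannot be told apart from a change inside the cells. The gate and any mix of cell types would change together in these libraries, and no library separates them.

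The S libraries differed from each other more than the other pairs. Depth does not account for it, since with thinned libraries the SD of the log2 difference over 11554 genes of at least 10 CPM was 0.311 in S, against 0.215 in G2M and 0.222 in G1, a ratio of S to G2M of 1.44. A candidate explanation is that S replicate 2 holds more cells near the G2M state. Over the 10226 genes called between G2M and G1, the slope of S minus G1 on G2M minus G1 was 0.597 for S replicate 2 and 0.488 for S replicate 1, a difference of 0.108 that barely clears the bar of 0.1 and has no error attached. With the G1 libraries split so that no library enters both axes, the slopes were 0.555 and 0.453. Whether the difference lies in the gates or the plants is open.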
